A study of Mus musculus with 473 samples.

How the data were processed

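RNA of single cells was measured with Smart-Seq2, a full-length poly(A) method, in 473 cells sorted by fluorescence from Th:EGFP mice, a bacterial artificial chromosome line in which regulatory sequences of tyrosine hydroxylase (Th) drive enhanced green fluorescent protein (eGFP), kept on the outbred Swiss Webster background. Per the labels' protocols, tissue of 4 embryos (embryonic day 15.5, E15.5) or of 5 pups (postnatal day 7, P7) was pooled for each region before papain dissociation, so a group is 1 pool of animals. The regions were forebrain (FB, in the labels the hypothalamus), midbrain (MB) and, at P7 alone, olfactory bulb (OB). P7 tissue was dissociated for longer and passed through a density gradient, which E15.5 tissue was not. Cells with eGFP fluorescence that excluded propidium iodide were sorted singly into wells. The libraries went through 20 preamplification cycles and 14 enrichment cycles at both ages.

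The deposited table holds FPKM values (by definition, fragments per kilobase of transcript, scaled to the mapped fragments of each library) that the authors made with HISAT2 and Cuffnorm on the mouse genome build mm10, per the submitters' processing notes. How each cell was in fact scaled is not known, and the sums per cell differed, as described below. Versions and the annotation release were not given in the sources used here. The table has 28952 features, of which 28636 could be given a symbol through GENCODE M21 (build GRCm38, the same assembly as mm10), 20508 of them at the same version of the Ensembl identifier, and 1 is the eGFP transgene. A symbol was shared by 14 features, and Kiss1 and Fam200b, members of the lists described here, were not analysed here. Coordinates come from GENCODE M21. FPKM is not a count, and the low values did not fall in steps of whole fragments when checked, so the depth of each cell is unknown; the number of genes detected per cell, given in the labels, stands in for it. Values of exactly 0 also occur for Actb, Actg1, Eef1a1, Tubb5, Gapdh and Hsp90ab1 (1.59% of E15.5 FB values, 0.758% of E15.5 MB, 0.538% of P7 FB, 1.04% of P7 OB and 0 in P7 MB), so a gene with no value above 0 is described as listed at 0, and no fold is given against it.

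Cells were grouped by the age and region in the labels. The labels also give for each cell the authors' quality verdict, the library plate, the number of genes expressed and 1 of 13 clusters. Of the 473 cells, 396 passed the quality control of the authors and 77 did not. The number of genes in each label was compared with the number of genes at FPKM of 1 or more in the column of the same name. On 3 of the 5 library plates the correlation across cells was at least 0.9, the minimum set for a match. On 2 of the 3 P7 plates the correlations were -0.0338 (95 cells) and -0.0519 (94 cells), and these 190 cells, 147 of them passed, were left out because their columns did not match the labels of the same name. Exchanging the names of these 2 plates well by well restored the match, as described below. The analysis therefore rests on 249 cells, 84 of E15.5 FB, 88 of E15.5 MB, 31 of P7 FB, 30 of P7 MB and 16 of P7 OB. Leaving out these plates departs from the design fixed before the data were examined, which used all 3 P7 plates; values by column name over all 3 are given as an alternative that was added after the data were seen. No 2 analysed cells had identical columns. No doublet caller was run, since the wells were filled by sorting.

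For each of 6 comparisons and each gene, the mean FPKM over cells was taken in both groups and expressed as log2((mean + 1)/(mean + 1)). Folds on this scale understate the difference of genes with low values. Cells of 1 pool are not replicates, so no test was made and no p-value or standard error is given. The SD is the spread over cells. List genes with a mean of at least 10 and at least 50% of it from 1 cell were looked for after the values had been seen. A cell was counted as having a gene at FPKM of 1 or more, and shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. The genes named per comparison were the 10 highest and the 10 lowest by log2 fold among genes with a mean of at least 20 in the higher group, found in at least 50% of its cells, and in the same direction on every library plate used and in the mean of log2(FPKM + 1). Within P7, where 1 plate was used, the plate condition was always met. Clusters were described by the 5 genes with the largest fold against the other cells of their group under the same minimums. Th was named in every group.

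The 28 gene lists were fixed before the data were examined. They cover dopamine synthesis, storage and reuptake; midbrain dopaminergic identity; hypothalamic transcription factors; hypothalamic peptides and receptors; olfactory bulb interneuron identity; GABAergic, glutamatergic, noradrenergic, serotonergic and cholinergic markers; immature neurons; the cell cycle; synaptic vesicle release; neuronal ion channels; axon guidance; oxidative phosphorylation; substantia nigra; ventral tegmental area; periaqueductal and dorsal raphe dopaminergic neurons; immediate early and stress genes; astrocytes, oligodendrocyte lineage, microglia, endothelium and pericytes, erythroid cells and radial glia; and 2 lists of Parkinson disease genes, Mendelian and association-locus. A member counted as measured with a mean FPKM of at least 1 in either group. For each list the median log2 fold, the members at least 2-fold apart and, with 3 or more measured members, the percentile of the median among 10000 random lists of the same size drawn from 20 expression bins were computed. The percentile describes these libraries and is not a test. Single-gene values of 4 list members are not reported here, while list medians include them. The 2 lists whose medians answer each comparison in the part on processing were picked after the medians had been seen.

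A cluster was called X-like from markers fixed in the same way, where at least 3 were detected and the cluster led its group in their median. Where such medians were close, a leading cluster could still be left unnamed, a judgement with no limit set beforehand. Clusters were made by the authors from these cells, so their leading genes describe them.

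The calculation was tested on simulated data. With 200 genes raised or lowered 2-fold in simulated cells of E15.5 MB against E15.5 FB (13582 genes), 99.5% had the right direction with a median log2 fold of 1.02, and with 4-fold it was 100% and 1.95. For P7 MB against P7 FB (12163 genes) it was 96.0% and 0.99 at 2-fold, and 100% and 1.99 at 4-fold. Lists of 15 raised genes had a percentile of 100, and lists of unchanged genes 26.1, 62.8, 54.3 and 9.64. The genes changed or listed in this simulation had a mean of at least 20 and were found in at least 50% of cells. Their spread was independent between cells, and no difference between pools was simulated. The simulation therefore says nothing about list members with lower means or carried by 1 cell.

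The alternatives were pseudocounts of 0.1 and 10, the mean of log2 values, rescaling of each cell to a sum of 1000000, all cells of the plates used with failed ones included, clusters weighted equally, no minimum or a minimum of 10 for list members, and each library plate alone. The P7 plates by column name, a rescaling without the transcripts AY036118 and Gm42418, leaving out the P7 FB cell with the most Slc6a3, and leaving out the highest cell of each gene in both groups were added after the data were seen. Leaving out the highest cell takes a larger share of a small group than of a large one. By construction it therefore tends to lower genes carried by few cells more in the smaller group. A value counts as having moved at a ratio of 1.5 or more, a limit that was also set after the values had been read in. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.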

Results

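RNA was measured in single Th:EGFP-positive cells of the mouse forebrain, midbrain and olfactory bulb at E15.5 and P7, and the labels name the choice of candidate genes for sporadic Parkinson disease as the purpose. Values of 249 cells were compared: 84 cells of E15.5 FB, 88 of E15.5 MB, 31 of P7 FB, 30 of P7 MB and 16 of P7 OB. Each group came from 1 pool of animals, so differences between groups have no replicate check, and values are means ± SD over these cells. In the analysed cells, the labels gave a median of 5554.5 genes per cell in E15.5 FB, 6227.5 in E15.5 MB, 5164 in P7 FB, 6126.5 in P7 MB and 3310.0 in P7 OB. The P7 values rest on 1 of 3 library plates, because the gene counts in the labels did not match the columns of the other 2 (correlations of -0.0338 and -0.0519, against 0.999 on the plate used).

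**Figure D1:**
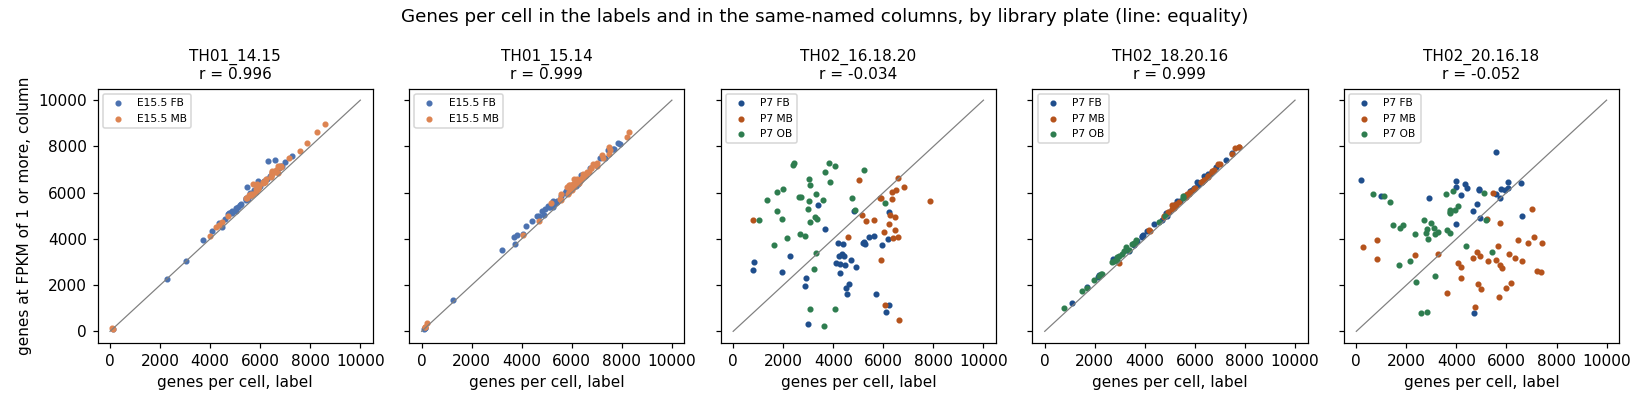
Genes per cell in the label (horizontal axis, number of genes) against genes at FPKM of 1 or more in the column of the same name (vertical axis, number of genes) for each library plate, with 1 point per cell and a line of equality. Points follow the line on 3 plates (correlations 0.996, 0.999 and 0.999) and scatter on 2 P7 plates (-0.0338 and -0.0519).

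Th (ENSMUSG00000000214.10; mm10 chromosome 7, 142892752 to 142931128, minus strand), which encodes the rate-limiting enzyme of dopamine synthesis and whose regulatory sequences drive the sorted reporter, was found in a minority of E15.5 cells and nearly all P7 cells. At E15.5 it was found in 27 of 84 FB cells (32.1%, 95% interval 22.4 to 43.2%) and 26 of 88 MB cells (29.5%, 20.3 to 40.2%). At P7 it was found in 30 of 31 FB cells, 29 of 30 MB cells and 16 of 16 OB cells. Mean Th was 137 ± 378 FPKM in E15.5 FB, 882 ± 3416 in E15.5 MB, 781 ± 1120 in P7 FB, 2341 ± 1399 in P7 MB and 1725 ± 1357 in P7 OB. The eGFP transcript of the reporter was found in 15.5% of E15.5 FB cells and 19.3% of E15.5 MB cells, and at P7 in 71% of FB, 90% of MB and 81.2% of OB cells. Slc6a3, the plasma membrane dopamine transporter, averaged 0.687 ± 5.10 in E15.5 FB, 230.3 ± 1065 in E15.5 MB, 119 ± 630.2 in P7 FB, 1193 ± 1359 in P7 MB and 138 ± 234 in P7 OB. In P7 FB, 1 cell at 3513 carried 95.5% of the Slc6a3 total, and the mean of the others was 5.47. The same cell, looked at after the values were seen, was the 1 FB cell with En1 (37.1), had Th at 4569 and was listed at 0 for Isl1 and Gad1. It was the highest FB cell for 6 of 10 midbrain identity genes with a mean of 1 or more in FB.

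**Figure D2:**
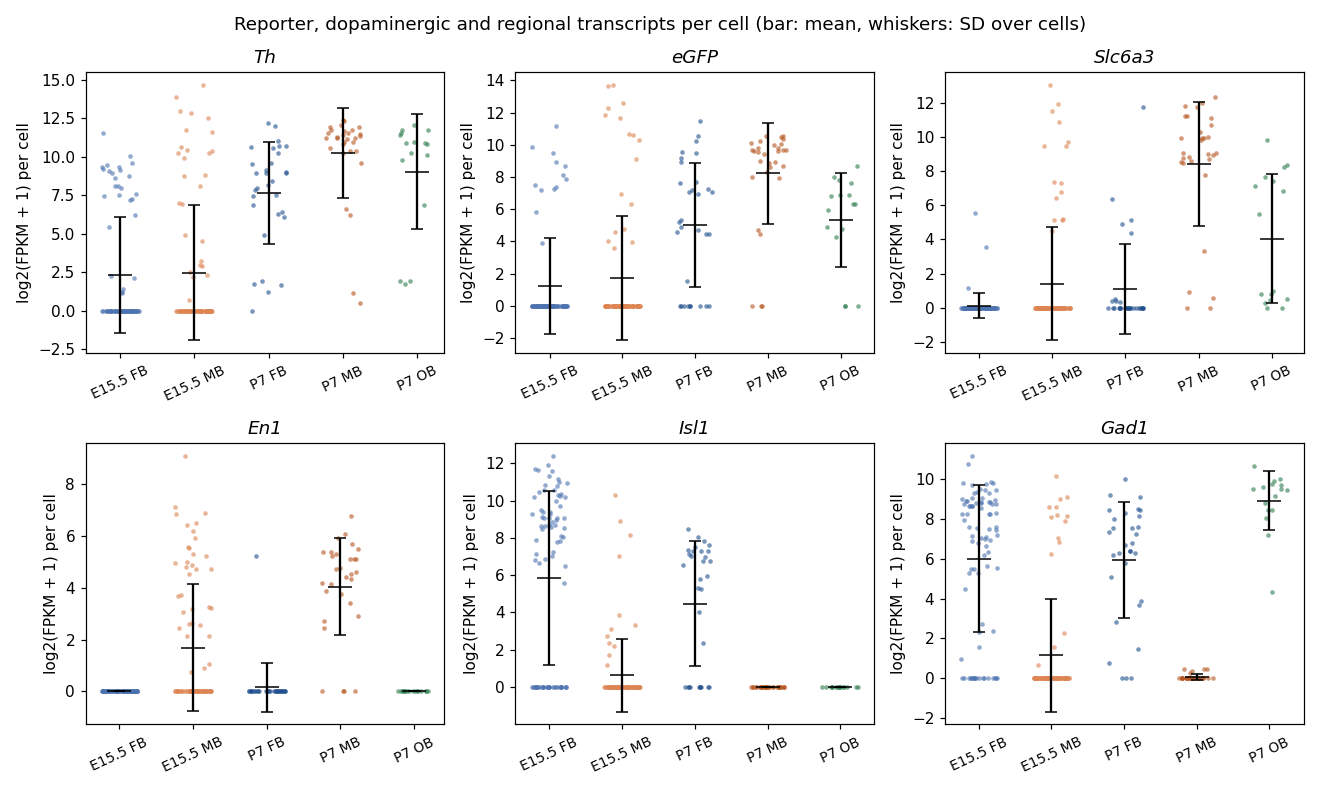
Levels per cell, as log2(FPKM + 1), of Th, eGFP, Slc6a3, En1, Isl1 and Gad1 in the 5 groups, with 1 point per cell, a bar at the mean and whiskers of 1 SD (whiskers can reach below 0, points do not); En1, Isl1 and Gad1 were picked after their values were seen. Th lies at 0 in most E15.5 cells and above 0 in nearly all P7 cells, En1 is seen mostly in MB, Isl1 mostly in FB, and Gad1 in 87.1% of P7 FB and 100% of P7 OB cells.

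The regional comparison at E15.5 asked how Th:EGFP cells of the midbrain differ from those of the forebrain. Most genes of the midbrain dopaminergic identity list were higher in MB, and the GABAergic genes and most hypothalamic transcription factors were higher in FB. Lhx9 (ENSMUSG00000019230.14; chromosome 1, 138825186 to 138848577, minus strand), a LIM-homeodomain transcription factor, was 52.9-fold higher in MB (112 ± 158 against 1.14 ± 6.39) and was found in 53.4% of MB cells (42.5 to 64.1%) and 4.76% of FB cells (1.31 to 11.7%). Isl1 (ENSMUSG00000042258.13; chromosome 13, 116298281 to 116309689, minus strand), another LIM-homeodomain factor, was 25.5-fold higher in FB (658 ± 1013 against 24.9 ± 146, of which 1 MB cell gave 57.8%), where 63.1% of cells (51.9 to 73.4%) had it, against 13.6% of MB cells (7.25 to 22.6%). Folds on log2(mean + 1) understate low genes.

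Of the midbrain dopaminergic identity list, 11 of 15 measured members were at least 2-fold higher in MB and none was lower, with a median log2 fold of 3.38 and a percentile of 100 among matched random lists. Its largest folds were those of Chrna6, a nicotinic receptor subunit of dopaminergic neurons (129 ± 419 against 0.359 ± 2.92, log2 fold 6.58), the transcription factor Pitx3 (107 ± 277 against 0.880 ± 8.07, 5.85) and Aldh1a1, a retinaldehyde dehydrogenase (230.1 ± 1248 against 3.77 ± 33.9, 5.60). Lmx1a followed (42.6 ± 121 against 0.10 ± 0.92, 5.31). In FB, 1 cell gave all of the Pitx3 total and 1 cell 98.0% of the Aldh1a1 total. Without that cell the log2 folds were 6.76 and 7.75, so the order of these genes rests on single cells. With the highest cell of each gene left out in both groups, a step chosen after the values were seen, 11 of 15 were still higher (median 3.16). En1 averaged 19.0 ± 63.5 in MB and was listed at 0 in FB. Dopamine synthesis, storage and reuptake genes had a median of 1.32 (6 of 10 higher, 0 lower), with Slc6a3 at 7.10, the cofactor enzyme Gch1 at 3.41 and the vesicular transporter Slc18a2 at 2.11. Substantia nigra genes had a median of 1.06 (6 of 11 higher, 1 lower) and ventral tegmental genes 0.94 (6 of 12 higher, 2 lower), with Otx2 at 4.06. The vesicular glutamate transporter Slc17a6, the 1 measured member of the glutamatergic list, was found in 75% of MB and 19.0% of FB cells (120.1 ± 157 against 19.7 ± 59.9, log2 fold 2.55).

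Among other genes named by rule, Nrn1, a neurite-growth protein, had a log2 fold of 3.01, the zinc transporter Tmem163 2.87, the sorting receptor Sorcs2 2.87, the transcription factor Ebf1 2.70, and Mab21l1 2.64. Timm8a1, a mitochondrial import protein, the protocadherin Pcdh18 and Klhl1 followed with 2.40, 2.29 and 2.16.

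In FB, 10 of 12 measured hypothalamic transcription factors were at least 2-fold higher than in MB (median log2 fold of MB over FB -2.72, percentile 0; 8 of 12 and -2.92 with the highest cells left out), among them Fezf1 (55.7 ± 279 against 0.0785 ± 0.736). Six3 (43.7 ± 76.4) and Lhx8 (45.8 ± 204) were listed at 0 in MB. GABAergic genes were lower in MB in 5 of 5 cases (median -1.44), with Gad2 and Gad1, which synthesise GABA, at -2.76 and -2.58. The homeobox genes Dlx5, Dlx1 and Dlx2 of forebrain GABAergic neurons had log2 folds of -3.90, -3.59 and -3.33 and belong to the olfactory bulb interneuron list (median -2.93, 10 of 14 lower). Ecel1, a membrane metalloprotease (ENSMUSG00000026247.13; chromosome 1, 87147655 to 87156521, minus strand), was 17.8-fold higher in FB (509 ± 786 against 27.6 ± 121). The kinase Map3k1 (-3.36), Gm14204 (-3.16), Islr2 (-2.87) and the choline transporter-like Slc44a5 (-2.78) were lower in MB as well. Hypothalamic peptides and receptors were mixed (median -0.98, plates -1.93 and -0.38, 4 of 15 higher and 7 lower in MB), with Npy at 402 ± 1979 in FB, 50.3% of it from 1 cell, and 8.55 ± 71.2 in MB. Single cells carried many of these genes: in MB 96.8% of Ghrh, 93.2% of Sst and 97.3% of Crh, and in FB 98.5% of Pomc and 99.2% of Avp. With the highest cells left out, 2 of 15 were higher and 7 lower (median -0.69), and Ghrh turned from 1.51 to -1.53.

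Synaptic vesicle genes (median -0.04, 0 of 18 past 2-fold), oxidative phosphorylation genes (0.02, 0 of 21) and immature neuron genes (-0.09, 1 of 17 higher and 2 lower) lay near 0. Both library plates of this age held both regions. The naming rule kept only genes with the same direction on each plate, and the midbrain identity median was 3.27 and 3.42 by plate. With the mean of log2 values in place of the log2 of means, the midbrain identity median was 0.93 and the hypothalamic factor median -0.51.

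At P7, the genes furthest apart between MB and FB under the naming rule were Vip, Aldh1a1 and Gad1. Vip, a neuropeptide (ENSMUSG00000019772.4; chromosome 10, 5639218 to 5647617, plus strand), averaged 1129 ± 3682 in MB and 0.296 ± 0.760 in FB and was found in 53.3% (34.3 to 71.7%) and 9.68% (2.04 to 25.8%) of cells. The 4 cells of cluster P7.MB.3 carried most of it (8347 ± 7132 against 18.1 ± 86.8 in the other MB cells). Aldh1a1 (ENSMUSG00000053279.6; chromosome 19, 20492715 to 20643465, plus strand) averaged 1113 ± 2029 in MB and 0.961 ± 5.18 in FB, and was found in 66.7% (47.2 to 82.7%) and 3.23% of cells. Gad1 (ENSMUSG00000070880.10; chromosome 2, 70553072 to 70602014, plus strand) was found at FPKM of 1 or more in 0 of 30 MB cells (a share of up to 11.6%), with values between 0 and 1 in 16.7%, and in 87.1% of FB cells (70.2 to 96.4%), with means of 0.0525 ± 0.123 and 184 ± 226.

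All 15 measured midbrain identity genes were at least 2-fold higher in P7 MB (median log2 fold 3.14, and 3.12 with the FB cell with the most Slc6a3 left out), including Chrna6 at 4.32, Foxa2 at 3.82, Pitx3 at 3.78 and Nr4a2 at 3.72. Without their highest FB cell, Chrna6, Pitx3 and Nr4a2 had log2 folds of 8.39, 5.31 and 5.02. With the highest cell of each gene left out in both groups, all 15 were still higher (median 3.66). Substantia nigra genes had a median of 2.74 (12 of 13 higher), with Igf1 at 3.65 (53.8% of its MB total from 1 cell and all of its FB total from 1 cell), Ndnf at 3.57 and Serpine2 at 3.43. Ventral tegmental genes had a median of 2.03 (9 of 12 higher, 1 lower), led by the neuropeptide gene Cck (965 ± 1084 against 13.9 ± 72.2, of which the same FB cell gave 93%, 6.01, or 8.91 without it). Of the periaqueductal list 4 of 6 were higher and 1 lower (median 1.51). Dopamine synthesis, storage and reuptake genes had a median of 1.43 (6 of 10 higher), with Slc6a3 at 3.32 (7.53 without the 1 FB cell that carried most of it), Slc18a2 at 2.73 and the receptor Drd2 at 2.09. Also higher in MB were Nwd2 (4.44), the growth factor binding protein Igfbp2 (4.24), the guidance cue Ntn1 (3.96), Nrn1 (3.89, or 5.78 without its highest FB cell), C130021I20Rik (3.83, an antisense transcript whose value is uncertain without strand information) and the mitochondrial gene Fam210b (3.82).

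In P7 FB, hypothalamic peptides and receptors were higher in 10 of 14 cases and lower in 1 (median -2.28), among them Ghrh, the growth hormone-releasing hormone (2447 ± 3990 in FB against 4.20 ± 10.5 in MB). Others were Npy (712 ± 3917 against 0.0506 ± 0.277), Sst (804 ± 3565 against 14.3 ± 73.3) and galanin, Gal (776 ± 1221 against 34.6 ± 76.2). In FB, 1 cell carried 98.8% of the Npy total and 1 cell 77.4% of the Sst total, and without its highest cell Npy had a log2 fold of -3.18. In MB, 1 cell carried 93.4% of the Sst total, and the log2 fold of Sst was -5.71, or -3.62 without the highest FB cell and -8.67 without the highest MB cell. All 9 measured hypothalamic transcription factors were higher in FB (median -2.30), 7 of them with the highest cells left out (-1.42); Isl1 averaged 89.1 ± 93.8 there and was listed at 0 in MB. GABAergic genes had a median of -3.05 (3 of 5 lower in MB), and olfactory bulb interneuron genes -2.35 (11 of 13 lower, 1 higher). Dlx1 (-7.00), Gad2 (-6.33), Ecel1 (-5.41), Dlx2 (-5.38), Arhgap36 (-5.27), Mamld1 (-4.09) and the Ras exchange factor Rasgrf1 (-3.65) completed the genes highest in FB. By column name over all 3 P7 plates, the midbrain identity median was 1.33 and the peptide median -1.32.

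Against P7 OB, whose dopaminergic cells are interneurons that also make GABA, P7 MB had far lower GABAergic transcripts. Gad1 averaged 650.5 ± 398 in OB (100% of 16 cells, 79.4 to 100%), 619-fold higher than in MB. The 5 GABAergic genes were all lower in MB (median log2 fold -3.42), as were 13 of 14 olfactory bulb interneuron genes (median -5.70), with Dlx1 at -8.55, the ETS factor Etv1 at -6.77, Dlx2 at -6.55 and Pax6 at -6.36. The peptide gene Trh (1539.9 ± 1575 in OB against 6.35 ± 15.4 in MB) and the R-spondin receptor Lgr5 (ENSMUSG00000020140.15; chromosome 10, 115450311 to 115587780, minus strand; 729 ± 770.2 against 5.66 ± 21.7) were among the 10 genes highest in OB. So were Gad2 (-7.42), the vesicle protein Synpr (-6.27) and Gm3764, which was listed at 0 in MB.

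Midbrain identity genes were higher in P7 MB in 14 of 15 cases (median log2 fold 4.19 over OB), with Aldh1a1 at 9.63, Chrna6 at 8.30 and Slc10a4 at 5.45 (98.4% of its OB total from 1 cell). Ventral tegmental genes had a median of 4.05 (10 of 11 higher, 1 lower), substantia nigra genes 3.26 (11 of 13 higher, 1 lower) and periaqueductal genes 4.63 (5 of 6 higher). The transcription factor Foxp2 (260.2 ± 257 against 0.126 ± 0.347), the nicotinic subunit Chrnb3 (6.67), the adhesion molecule Cadm1 (6.49), the calcium sensor Hpcal1 (6.47), Plcxd3 (6.36) and the cadherin Cdh8 (6.33) were higher in MB, with Vip at 6.94 (9.40 without the OB cell that gave 92.3% of its total there). For Cadm1, 1 OB cell gave 70.4% of the OB total, and without it the log2 fold was 7.53. Tspan17 (83.5 ± 72.7 in MB) was listed at 0 in OB. P7 OB cells had fewer genes detected than P7 MB cells (medians of 3310 and 6126.5 in the labels). How far this shaped the values against OB was not tested. Dopamine genes had a median of 2.77 (7 of 10 higher), although Th itself averaged 2341 in MB and 1725 in OB. Rescaling each cell to the same total gave 4.90 for midbrain identity and -6.43 for olfactory bulb identity, the highest cells left out gave 4.07 and -5.38, and the 3 plates by column name gave 1.04 and -0.87. With the column names of the other 2 plates exchanged well by well, a step chosen after the data were seen, olfactory bulb identity was -3.82 and -4.50 on these plates.

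Gad1 was found in most cells of both P7 FB and P7 OB, and these groups differed in hypothalamic peptides and in bulb-specific factors. Peptides and receptors were at least 2-fold higher in FB in 12 of 15 cases and lower in 3 (median log2 fold 2.35), with Asb4, a ubiquitin ligase subunit of hypothalamic neurons, at 6.70, and Ghrh (2447 ± 3990) and the calcitonin receptor Calcr (69.5 ± 111) listed at 0 in OB. Trh (-5.68) and Crh (-5.98) went the other way, as did Agrp (-1.78), with 97.9% of its OB total from 1 cell. With the highest cells left out, 10 of 15 peptide genes were higher and 3 lower (median 2.48). In FB, 1 cell gave 98.8% of the Npy total, and without it Npy turned from 1.46 to -4.77. For Oxt 1 FB cell gave 93.5% of the total, and without it the log2 fold fell from 2.35 to 0.35. Hypothalamic transcription factors had a median of 1.86 (8 of 10 higher, 2 lower). The 2 lower ones, Lhx8 and Nkx2-1, came from 1 OB cell each, and with the highest cells left out 7 of 10 were higher and 0 lower (1.40). Ventral tegmental genes had a median of 2.75 (8 of 11 higher, 1 lower), or 1.90 with the FB cell with the most Slc6a3 left out and 1.37 with the highest cells left out. Ecel1 (289 ± 229), the mitochondrial carrier Ucp2 (198 ± 309), Arhgap36 (155 ± 263), Tspan17 (126 ± 129), Saxo2 (90.8 ± 167), Isl1 (89.1 ± 93.8) and Eif1a (60.8 ± 89.4) were all listed at 0 in OB, while Hpcal1 (6.44) and Cadm1 (6.19) were higher in FB. Without the OB cell that gave 70.4% of the Cadm1 total there, the Cadm1 log2 fold was 7.23.

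In OB, Lgr5 was 176-fold higher than in FB, the metallothioneins Mt2 and Mt1 had log2 folds of -6.50 and -5.84 (FB over OB), and Pcp4l1 (-6.12), the phosphodiesterase Pde1c (-6.09) and the guidance cue Sema3e (-5.01) were higher as well. Eya2 (73.2 ± 102) and Shisa8 (66.1 ± 70.6) were listed at 0 in FB. Olfactory bulb interneuron genes were lower in FB in 11 of 14 cases (median -1.52), with Sall3 at -5.14, Pax6 at -4.82 and Synpr at -4.20, and GABAergic genes in 4 of 5 (median -1.33). In FB, 1 cell gave 96.8% of the Pax6 total, and without it the Pax6 log2 fold was -7.12. These values rest on 16 OB cells and 31 FB cells of a single plate. Fewer genes were detected per cell in OB than in FB (medians of 3310 and 5164 in the labels), and the effect of this was not tested. By column name over 3 plates the medians were 1.07 for peptides and -0.15 for olfactory bulb identity. With the column names of the other 2 plates exchanged, the peptide median was 4.03 and 1.82 on these plates.

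**Figure D3:**
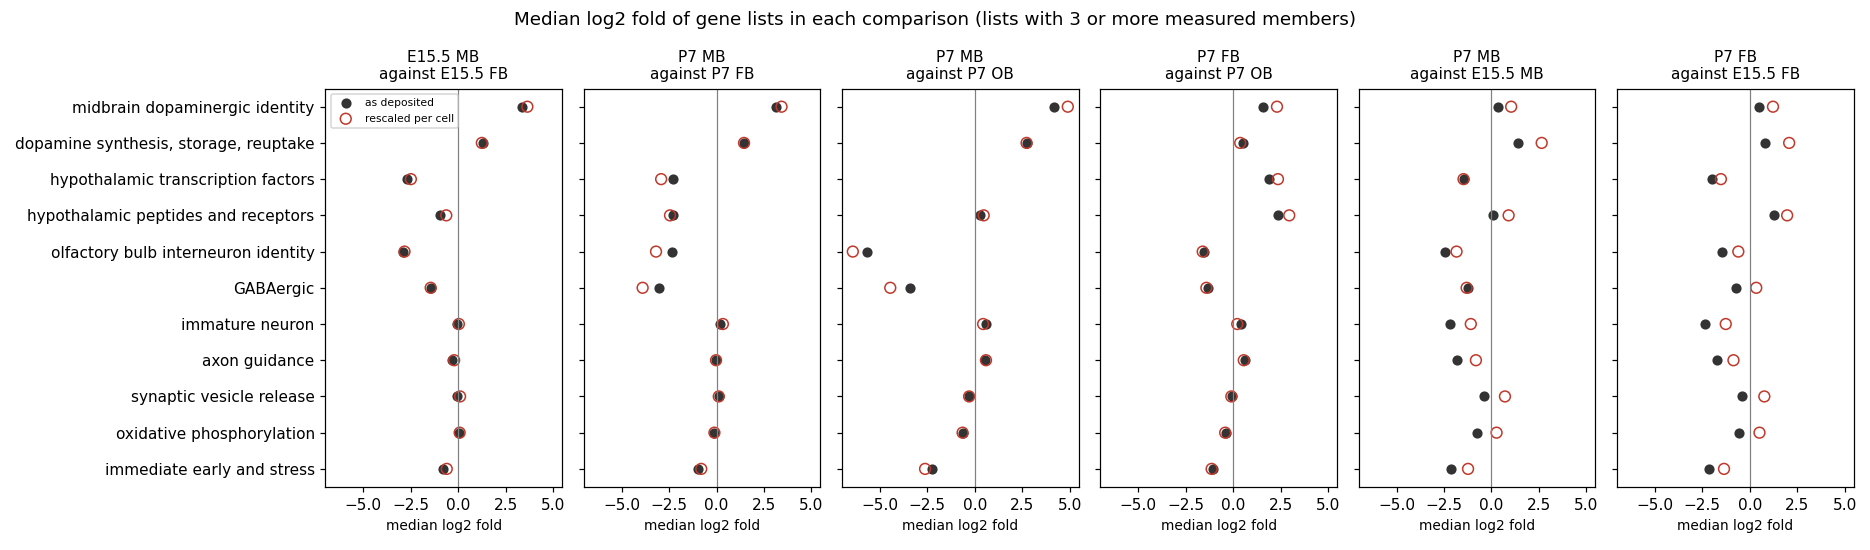
Median log2 fold (horizontal axis, log2 units) of 11 gene lists (vertical axis) in the 6 comparisons, filled circles as deposited and open circles after each cell was rescaled to the same total; lists with under 3 measured members are left out of a panel. In the age comparisons most open circles lie to the right of the filled ones, and those of synaptic and oxidative phosphorylation genes lie on the other side of 0.

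P7 was compared with E15.5 within each region, to describe what differs between embryonic and postnatal Th:EGFP cells. The median log2 fold of all genes was -1.18 in MB and -1.20 in FB as deposited, and -0.33 and -0.31 with every cell rescaled to the same total, so folds are given relative to the median of all genes. In MB the immature neuron list was lower at P7 (relative median -0.99, 15 of 17 members at least 2-fold lower as deposited and 9 after rescaling). The cytoskeletal gene Dcx was at 10.7 ± 12.4 against 230 ± 180, the transcription factor Sox11 at 1.95 ± 3.73 against 74.6 ± 69.9 and Cd24a at 49.5 ± 81.2 against 1037 ± 762. Axon guidance genes lay at -0.65, with Ephb1 at 9.62 ± 15.2 against 104 ± 140. Dopamine synthesis, storage and reuptake genes lay at 2.59, ventral tegmental genes at 3.13, substantia nigra genes at 2.25 and periaqueductal genes at 3.11. Synaptic vesicle genes were -0.39 as deposited and 0.79 relative to all genes, and oxidative phosphorylation genes were -0.78 and 0.40, so both change sides with the scale.

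Among genes named by rule, Vip had the largest relative log2 fold in MB (10.82), found in 53.3% of P7 and 5.68% of E15.5 cells. The neurotrophin gene Ntf3 (6.04, all of its E15.5 total from 1 cell), A230050P20Rik (5.85), Omg, a myelin-associated surface glycoprotein (5.51), the calcium-binding protein Calb1 (5.39), the zinc transporter Slc39a4 (5.19), the claudin Cldn1 (4.78) and the tubulin Tuba4a (4.50) followed. Ass1 (5.19) and Gm5424 (4.66) share sequence, and their values are uncertain for that reason. At E15.5, Cdkn1c (ENSMUSG00000037664.12; chromosome 7, 143458339 to 143461050, minus strand), a cyclin-dependent kinase inhibitor, averaged 126 ± 151 and was listed at 0 in P7 MB. Relative log2 folds were -5.53 for the glypican Gpc2, -4.72 for Epb41, -4.49 for the histone methyltransferase Ezh2 and -4.15 for the splicing repressor Ptbp1. They were -3.88 for the phosphatase Dusp4, -3.87 for Runx1t1, -3.59 for Sema4c and -3.57 for Trp53i11. Slco5a1 (33.7 ± 55.8) was listed at 0 at P7. With clusters weighted equally in each group, the median of dopamine genes as deposited, not relative to all genes, was -0.22 (1.41 with cells weighted equally, where all genes lay at -1.18). In the E15.5 MB group 68 of 88 cells belonged to a cluster with few Th transcripts.

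In FB, the immature neuron list was again lower at P7 (relative median -1.14, 15 of 17 members lower as deposited, 11 after rescaling). Igfbpl1, a secreted protein of neuronal precursors (ENSMUSG00000035551.6; chromosome 4, 45809468 to 45826923, minus strand), averaged 117 ± 159 at E15.5 and 0.215 ± 0.845 at P7 (relative log2 fold -5.40). The nuclear receptors Nr2f1 (-4.66) and Nr2f2 (-4.30), the matrix protein Vcan (-4.37), Ankhd1 (-4.08), Gpc2 (-4.04), B3gnt5 (-4.02), Cd24a (-3.91), Shkbp1 (-3.82) and the nuclear lamin Lmnb1 (-3.73) were lower too. Cell cycle genes had a relative median of -1.03, axon guidance genes -0.55 and hypothalamic transcription factors -0.82.

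Higher at P7 in FB were Ucp2 (relative 6.27), Arhgap36 (5.53), the GABA receptor subunit Gabre (5.26), Tuba4a (5.05), the glutathione peroxidase Gpx3 (4.82), Cpne6 (4.82), Omg (4.81), Aldoc (4.63), Rwdd2a (4.40) and Igsf1 (4.31). Hypothalamic peptides had a relative median of 2.47, with Ghrh at 2447 ± 3990 against 23.8 ± 155 (65.3% of it from 1 cell), the growth hormone receptor Ghr at 18.9 ± 38 against 0.887 ± 5.69 and Trh at 29 ± 50.3 against 1.13 ± 9.05. As deposited the peptide median was 1.28 (8 of 16 higher, 4 lower), and with the highest cells left out it was 0.40 (6 higher, 1 lower). Dopamine genes lay at 2.02 with Th at 781 against 137, synaptic vesicle genes at -0.40 as deposited and 0.80 relative, and oxidative phosphorylation genes at -0.59 and 0.61. Age went with sort day, sequencing run, library plates, dissociation time and the gradient, and the effects of these and of age cannot be told apart.

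The 13 clusters of the authors describe cell types within each group, and their leading genes are not tests. At E15.5, 20 of 88 MB cells formed E15.MB.2 (22.7%, 14.5 to 32.9%), midbrain dopaminergic-like, led by eGFP (2488 ± 4128 against 3.07 ± 15.2), Slc6a3 (1005 ± 2092), C130021I20Rik, Lmx1a (187 ± 195) and Chrna6 (558 ± 742). The other 68 cells, E15.MB.1, were led by Lhx9 (145 ± 167), Pax5 (182 ± 261), Evx1 (40.9 ± 82.1), Syn2 and Pcdh9. Th averaged 3779.6 in E15.MB.2 and 29.6 in E15.MB.1. In E15.5 FB, E15.FB.1 (60 cells) was led by Rnd3, Fam84a, Tmtc4, Dcc and Vsnl1, and E15.FB.2 (24 cells) by Eepd1, Npy, Esrrg, Gm5532 and Gas1. Neither was named, since E15.FB.1 led in several marker lists and the neuroblast medians were close (7.16 and 7.84 on the log2 scale). In P7 FB, Ghrh (7368 ± 3626 against 104 ± 306) and the estrogen receptor Esr1 (84.3 ± 76.7 against 1.55 ± 6.74) led P7.FB.1 (10 cells), and Vstm2a, Lingo2, Spock1 and Pde4b led P7.FB.2 (21 cells).

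Among 16 P7 OB cells, P7.OB.1 (5 cells) was neuroblast-like, with Calb2 (3520 ± 3559 against 0.160 ± 0.360), the peptide gene Crh and the transcription factor Nfib among its leading genes. P7.OB.2 (5 cells) and P7.OB.3 (6 cells) had 8 of 8 olfactory bulb interneuron markers. Their leading genes were Gm15860, Zfand1, Btg2, Cyp4f16 and Ipmk in P7.OB.2, and Dusp14, Mpv17, Slc35d3, Smyd2 and Sri in P7.OB.3. In P7 MB, P7.MB.1 (15 cells) was ventral tegmental-like, led by Gpr83, Casr, Otx2, Shisa2 and Lpl. P7.MB.3 (4 cells) was periaqueductal-like, led by Vip (8347 ± 7132 against 18.1 ± 86.8), Crhbp, Mbnl3, Prkcd and Tdh, and P7.MB.4 (7 cells) was substantia nigra-like, led by Fam19a4, Aldh1a7, Rgs6, the growth factor Fgf20 and Aldh1a1 (4172 ± 2142 against 182 ± 539). P7.MB.2 (4 cells) had a neuroblast median of 3.14, against 2.91 in P7.MB.1. It stayed unnamed because these medians were close, although the rule asks only for the lead. P7.MB.2 was led by Meis2, Sst (93.4% of its MB total from 1 cell), Meis1 and Rprml, and had Th at 43.1 ± 49.7.

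The Parkinson disease lists were compared between the substantia nigra-like cluster P7.MB.4 and the other 23 P7 MB cells, since nigral neurons are those lost in the disease. The median log2 fold of Mendelian genes was 0.30 (2 of 18 higher and 1 lower, percentile 85.6), and of association-locus genes 0.19 (6 of 43 higher and 4 lower, percentile 78.6). Substantia nigra genes, with markers that also named this cluster, had a median of 2.37. Of the Mendelian genes, the protease Htra2 had a log2 fold of 1.29. Of the association-locus genes, Fgf20 (22.4 ± 11.7) was listed at 0 in the other cells, the corticotropin-releasing hormone receptor Crhr1 averaged 25.4 against 1.17 (3.61), the chromatin protein Satb1 was at 2.13, the complexin Cplx1 at 1.39 and the lysosomal protein Scarb2 at 1.37. Pla2g6 was lower (-1.18), and so were Tmem163 (-1.72) and Gch1 (-0.91). Of the Pla2g6 total in P7 MB, 61.5% came from 1 cell. The Setd1a log2 fold of 2.39 came from 1 cell.

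In the ventral tegmental-like P7.MB.1, Gch1 averaged 202 ± 168 against 32.5 ± 43.6 (2.60), and medians were 0.09 for Mendelian and 0.15 for association-locus genes. In P7.MB.3 the association-locus median was -0.99 (4 of 44 higher and 22 lower, percentile 0.14), with Cplx1 listed at 0, over 4 cells. Medians in P7.MB.2 were -0.23 and -0.27, also over 4 cells. These clusters were made by the authors from the same cells, and 4 to 15 cells per cluster limit the precision of each mean. Median genes per cell at FPKM of 1 or more were 6218 in P7.MB.1, 6088.5 in P7.MB.2, 5407.5 in P7.MB.3 and 7679 in P7.MB.4. The clusters stood in the same order by these gene counts as by their association-locus medians. Whether detection rather than cell type sets these medians was not tested.

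**Figure D4:**
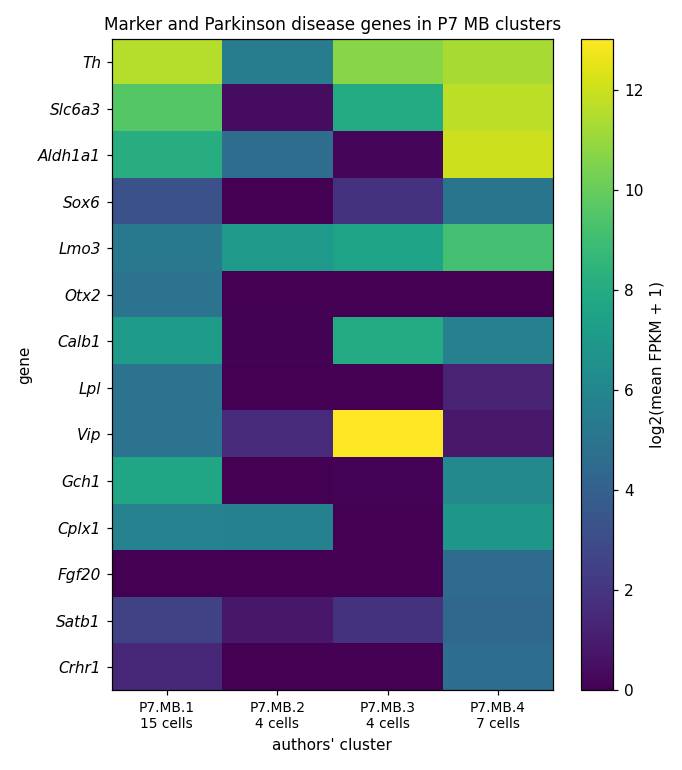
Heat map of log2(mean FPKM + 1) (colour scale) of 14 genes (vertical axis) in the 4 P7 MB clusters (horizontal axis, with 15, 4, 4 and 7 cells); genes were picked after their values were seen. Aldh1a1 is highest in P7.MB.4, Vip in P7.MB.3 and Gch1 in P7.MB.1.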

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

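The tests on library plates, on the FPKM scale and on lower depth in E15.5 MB cells, and the limits for values in failed cells, were chosen after the results had been seen. The test with Slc17a6 was set down before its value but after the clusters, Th and eGFP had been looked at.

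Calb1 stood out because the MB and FB difference at P7, with 1 plate used, was opposite to that on both E15.5 plates. Of the 88 E15.5 MB cells, 68 belonged to E15.MB.1, with few Th transcripts, so the E15.5 MB mean was mostly over such cells. At E15.5 Calb1, a calcium-binding protein, was lower in MB (5.34 against 30.4, log2 fold -2.31, plates -1.54 and -3.21), and at P7 it was higher in MB (116 against 40.9, 1.49), a difference of 3.80 that was not tested.

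Some P7 cells that failed quality control, which no comparison used, held glial transcripts well above the passed cells of their group. At E15.5, Mbp was 0 in failed cells of both regions, against 13.6 in passed FB and 20.6 in passed MB cells. Some failed E15.5 wells were nearly empty, for example with 101 and 134 genes in MB and 137 in FB. A value of 0 for 1 gene in such wells decides nothing about glial transcripts at this age. In P7 MB, Mbp averaged 6093 over 5 failed cells against 12.5 in 30 passed cells, with 1 failed cell at 30244. In 8 failed P7 OB cells, set against 16 passed ones, the astrocyte genes Aqp4 (136 against 0.0197), Gfap (349 against 0.0309), Slc1a3 (591 against 15.7), Aldh1l1 (125 against 0), Gja1 (431 against 0.129) and Aldoc (145 against 2.88) were high. So were the oligodendrocyte-lineage gene Olig1 (95.6 against 0) and the progenitor genes Fabp7 (5207 against 14.4), Hes1 (90.1 against 0) and Hes5 (22.8 against 0).

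On 2 P7 library plates, gene counts in the labels were unrelated to those in the columns of the same name. With the names of these plates exchanged well by well, the correlations were 0.9987 and 0.9992, and the median difference was 89 and 82 genes instead of 1748 and 1748.5, which is consistent with exchanged names. Wrong gene counts in the labels alone are argued against by the values: by column name the midbrain identity median of P7 MB over P7 FB was 0 on 1 plate and -2.70 on the other, against 3.14 on the matching plate and 2.62 and 3.18 after the exchange. En1, picked after its values were seen, was found by column name in 70.4% of OB cells on 1 of these plates and 90.5% of FB cells on the other, against 86.7% of MB cells on the matching plate. At which step names were exchanged stays open, and no biological explanation was tested.

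The sum of FPKM per cell had a median of 1007670.0 at E15.5 and 516099 on the matching P7 plate, a ratio of 1.95. A candidate explanation is a normalization that ties each cell to a few transcripts, since AY036118, at 61181 ± 3853 FPKM, varied by only 6.30% over cells, Gm42418 by 16.5% and the next of 1812 genes, Ywhaz, by 53.4%. Lower RNA content at P7 remains open, because the medians of the 3 P7 plates, whose cells came from the same pools, differed by 2.51 times, and this ratio decides nothing about ages that were never on 1 plate. Age and library plate cannot be told apart here.

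Most E15.5 MB cells, selected for the reporter, lacked its transcripts: Th was found in 19.1% and eGFP in 8.82% of E15.MB.1 cells, against 65% and 55% of E15.MB.2. A test set down earlier, on abundant transcripts of E15.MB.2, was at its ceiling (100% in both clusters) and decides nothing. Lower depth is argued against by 2411 genes found about as often as Th in E15.MB.2, dopaminergic lists left out: their share in E15.MB.1 over that in E15.MB.2 had a median of 1.08 (quartiles 0.941 and 1.2), against 0.294 for Th. Neurons of another type among the sorted cells remain possible, and Slc17a6 was found in 80.9% of E15.MB.1 and 55% of E15.MB.2 cells. Slc17a6 cannot decide this, because it was common in the dopaminergic-like cluster too and is on the ventral tegmental list. Most E15.5 FB cells also lacked the transcripts (Th found in 32.1%, eGFP in 15.5%), and Slc17a6 was less common there than in MB. Brief activity of the reporter, or protein that outlasts its transcript, stays open and was not tested.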

How the results depend on the processing

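The P7 plates by column name, the rescaling without AY036118 and Gm42418, leaving out the P7 FB cell with the most Slc6a3, and leaving out the highest cell of each gene in both groups were chosen after the data had been seen, and so were the ratio of 1.5 and the 2 results that answer each comparison. The other alternatives were set before the data were examined. Of 1719 list medians under an alternative, 1245 moved by less than 1.5 times, 456 by more and 18, from values at least 2-fold apart, changed direction. Of 1240 folds of named genes these were 661, 578 and 1. The P7 plates by column name take in the 2 plates whose names appear exchanged. They gave 10 of the 18 list medians that changed direction and 55 of the 456 that moved. They also gave 91 of the 578 named genes that moved and the 1 that changed direction. These cases reflect the naming of the columns more than the P7 results. Of 890 list medians from values under 2-fold, 130 had the other sign, 8 of them on 1 plate alone. Of 25 shares and counts, 23 stayed within their interval. With FPKM above 0 in place of 1, Th in P7 MB (100%) and Slc6a3 in P7 OB (87.5%) did not. No paired analysis was possible because each group is 1 pool and no result comes from a test. The P7 plates that do not match were run alone for 3 list medians, not for all results, and P7 MB clusters were not run by plate, as 1 matching plate holds them. Depth is unknown in FPKM; low genes and clusters of 4 cells are the least certain. Unless stated, the cause was not tested.

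For the results that answer the comparisons, the values that moved by more than 1.5 times were as follows, in the order E15.5 MB against E15.5 FB, P7 MB against P7 FB, P7 MB against P7 OB, P7 FB against P7 OB, P7 MB against E15.5 MB, P7 FB against E15.5 FB. A pseudocount acts on low values by construction. With 0.1, midbrain identity and hypothalamic factors were 5.89 and -3.38, midbrain identity and peptides 3.99 and -3.37, midbrain and olfactory bulb identity 6.98 and -8.06, and peptides 5.26. With 10, they were 1.46 and -1.0, 1.73 and -1.56, 1.67 and -2.61, and 1.43. Peptides in FB by age were 0.59, and substantia nigra genes in P7.MB.4 were 1.47. By the difference in mean log2, they were 0.93 and -0.51, peptides -1.05, 3.51 and -4.17, and peptides 0.71. Dopamine genes in MB by age were 3.90, and peptides in FB by age 0.60.

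Rescaled to the same total, midbrain and olfactory bulb identity in P7 MB against P7 OB were 4.90 and -6.43, and peptides in P7 FB against P7 OB 2.95. Dopamine and immature neuron genes in MB by age were 2.65 and -1.09, and peptides and immature neuron genes in FB by age 1.97 and -1.27. Rescaled without AY036118 and Gm42418 these were 5.09, -6.63, 3.11, 2.72, -1.0, 2.04 and -1.19. With clusters weighted equally, midbrain identity at E15.5 was 4.37. Without a minimum for list members, hypothalamic factors at E15.5 were -1.55. With a minimum of 10, which leaves fewer members, they were -5.08, peptides -4.45 (P7 MB against P7 FB) and 4.13 (P7 FB against P7 OB), and olfactory bulb identity -2.28 (P7 FB against P7 OB). On 1 plate alone, hypothalamic factors at E15.5 were -2.10 at the highest. By age, dopamine genes in MB were 0.70 and 2.20, and peptides in FB 2.38 at the highest. With the highest cell of each gene left out in both groups, peptides in FB by age were 0.40. That step takes a larger share of the smaller P7 group.

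By column name over 3 P7 plates, midbrain identity and peptides were 1.33 and -1.32 (P7 MB against P7 FB), midbrain and olfactory bulb identity 1.04 and -0.87 (P7 MB against P7 OB), and peptides and olfactory bulb identity 1.07 and -0.15 (P7 FB against P7 OB). Dopamine and immature neuron genes were 0.29 and -2.86 (MB by age), and immature neuron genes -3.00 (FB by age).

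Among values at least 2-fold apart, direction changed in these cases. With a minimum of 10, oligodendrocyte genes were -0.38 (P7 MB against P7 OB) and -0.57 (P7 FB against P7 OB). With failed cells included they were -1.34 (P7 FB against P7 OB) and 1.57 (FB by age). With clusters weighted equally, dopamine genes were -0.22 (MB by age). By the difference in mean log2, substantia nigra and periaqueductal genes were 0.16 and 0.30 (FB by age), and on the highest pairing of plates periaqueductal genes were 0.40. By column name over 3 plates, radial glia genes were 1.05 (P7 MB against P7 OB). The value of P7 FB against P7 OB: midbrain dopaminergic identity was -0.0950 (0.26 with the P7 FB cell left out, 1.57 with it), and in the same comparison periaqueductal genes were -0.14, oligodendrocyte genes -1.01 and Eya2 0.17. Olfactory bulb, GABAergic, astrocyte and radial glia genes were 0.80, 0.49, 0.98 and 0.36 (MB by age), and substantia nigra and periaqueductal genes 0.0139 and 0.80 (FB by age).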

Other observations

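The values in this part come from lists fixed before the data were examined and were not tested. Leaving out the highest cells tends to lower OB, which had fewer cells than MB or FB, more by construction. P7 OB cells also had fewer genes detected than P7 MB or P7 FB cells, and its effect on comparisons with OB was not tested. Immediate early and stress genes had median log2 folds below 0 in P7 MB against each of the other P7 groups. Against P7 OB, 9 of 11 were at least 2-fold lower (median log2 fold -2.24, percentile 0; 7 of 11 with the highest cell of each gene left out in both groups, a step chosen after the values were seen), with the transcription factors Egr1 at 3.29 ± 7.49 against 129 ± 141, Fos at 32.9 ± 47.95 against 228 ± 158 and Junb at 5.33 ± 13.4 against 45.97 ± 63.3. Against P7 FB, 5 of 11 were lower and 1 higher (median -1.0), with Ier2 at 1.19 ± 5.30 against 23.5 ± 84.99 (55.3% of the latter from 1 cell). P7 FB was lower than P7 OB in 7 of 11 (median -1.07), and at E15.5 MB was lower than FB in 5 of 12 (median -0.79, plates -1.14 and -0.18, 3 of 12 after rescaling and 2 of 12 with the highest cells left out). Relative to all genes, the list was lower at P7 than at E15.5 in both regions (-0.97 in MB and -0.97 in FB), with the phosphatase Dusp1 in MB at 16.1 ± 32.9 against 206 ± 214. All cells went through tissue dissociation, which was longer at P7.

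Oxidative phosphorylation genes were lower in P7 MB than in P7 OB in 6 of 21 cases and higher in none (median -0.64, percentile 0.04; 1 lower and -0.40 with the highest cells left out), with Ndufa4 at 878 ± 280 against 2476 ± 1943 and Cox6c at 436 ± 161 against 1022 ± 1068. Against P7 OB, P7 FB had a median of -0.39 (2 of 21 lower). Whether the lower number of genes detected per cell in P7 OB sets these medians was not tested. Neuronal ion channel genes had a median of 0.25 in E15.5 MB against E15.5 FB (4 of 25 higher, 1 lower, plates 0.05 and 0.09), with Kcnip4, a potassium channel partner, at 1.73. At P7 Kcnip4 averaged 88.1 ± 71.7 in MB, 17.9 ± 31.6 in FB and 8.21 ± 32.5 in OB, 99% of the last from 1 cell. Relative to all genes, ion channel genes were 0.30 higher at P7 in MB and 0.74 higher in FB. As deposited their medians by age were -0.88 in MB (1 of 25 higher, 10 lower) and -0.46 in FB (0 of 24 higher, 7 lower). Both medians thus change sides with the scale. Axon guidance genes were 0.54 in P7 MB against P7 OB (6 of 19 higher, 3 lower; 11 and 0 with the highest cells left out), with the guidance cue Slit2 at 40.2 ± 57.7 against 0.201 ± 0.761.

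Cholinergic, serotonergic and adrenergic markers were sparse. Slc18a3, a vesicular acetylcholine transporter and the 1 measured cholinergic gene, averaged 19.0 ± 48.4 in P7 FB and 0.0115 ± 0.0628 in P7 MB, a log2 fold of -4.30. The serotonergic gene Tph2 averaged 2.16 ± 8.74 in P7 MB (67.1% from 1 cell) and was listed at 0 in P7 FB and P7 OB, and the adrenergic gene Pnmt averaged 1.41 ± 7.82 in P7 FB (all from 1 cell) and was listed at 0 in P7 MB and P7 OB.

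Among markers of other cell types, differences rested on few measured genes. In P7 MB against P7 FB, astrocyte genes had a median of -1.33 (5 of 7 lower; 3 lower and 1 higher with the highest cells left out), with Aldoc at 14.18 ± 35.7 against 99.97 ± 113, while Sox9 (12.7 ± 41.05 in FB) was listed at 0 in MB. In FB by age, astrocyte genes lay at 2.84 relative to all genes (5 of 8 at least 2-fold higher at P7 and 2 lower as deposited). Their median as deposited was 1.65, and 0.44 with the highest cells left out. At E15.5, medians of MB over FB were -0.86 for oligodendrocyte-lineage genes (2 of 4 lower, plates -1.13 and 0.11), -0.95 for radial glia genes (3 of 7 lower, plates -1.31 and -0.34) and 0.72 for astrocyte genes (1 of 6 higher and 1 lower, plates -0.02 and 0.73). They were -0.19 for cell cycle genes (3 of 9 lower, plates -0.28 and -0.09), -0.31 for erythroid genes (1 of 3 lower, plates -0.88 and -0.29), 1.15 for microglia genes (2 measured, plates 0.40 and 1.60) and 1.01 for endothelial and pericyte genes (2 measured, plates 0.73 and 0.82). With the highest cells left out, 1 of 7 radial glia genes and 0 of 9 cell cycle genes were lower. C1qb of microglia averaged 1.39 ± 13.1 in MB, all from 1 cell, and was listed at 0 in FB.

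Medians of the Parkinson disease lists between MB and the other regions lay between -0.30 and 0.42. Mendelian genes had medians of -0.30 at E15.5 (MB over FB, 1 of 18 higher and 1 lower) and 0.29 at P7 (5 of 19 higher, 0 lower, percentile 98.99), and association-locus genes 0.05 (6 of 44 higher, 2 lower) and 0.03 (6 of 45 higher, 1 lower). Against P7 OB, the Mendelian median of P7 MB was 0.42 (4 of 18 higher, 1 lower, percentile 93.3) and the association-locus median -0.17 (13 of 44 higher, 11 lower). With the highest cells left out these were 0.75 (7 higher, 0 lower) and 0.33 (16 higher, 6 lower), and the association-locus counts at E15.5 and at P7 over FB were 10 and 11 higher and 0 lower. Because OB had fewer cells than MB, this step by itself tends to move the folds against OB toward MB. By age, Mendelian and association-locus genes lay at 0.37 and 0.41 in MB and -0.08 and 0.48 in FB relative to all genes. As deposited they were lower at P7, with medians of -0.81 (2 of 18 higher, 7 lower) and -0.77 (3 of 43 higher, 18 lower) in MB. In FB these were -1.28 (1 of 18 higher, 10 lower) and -0.72 (5 of 43 higher, 18 lower). All but the Mendelian median in FB thus change sides with the scale.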
